A study of Arabidopsis thaliana with 16 samples.

How the data were processed

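RNA was profiled in 7 groups of Arabidopsis Ws-0 material at the heart stage: 6 compartments (embryo proper, micropylar, peripheral and chalazal endosperm, chalazal seed coat and seed coat) and whole seeds, all taken from sections by laser capture microdissection. Per the labels, seeds held embryos 52 to 85 micrometres long and came from siliques of 1.2 to 1.5 cm on plants 38 to 46 days old. Amplification started from 5 to 6 ng of RNA per sample, and the product was labelled with biotin and hybridised to an Affymetrix ATH1 array. The chalazal endosperm and the chalazal seed coat had 3 arrays each and the other groups 2 each, 16 in all. The labels call these biological replicates and do not say whether compartments share plants, so replicate numbers were not used to pair samples.

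The authors processed the arrays with the Affymetrix GCOS software, whose version and algorithm settings are not given in the sources used here. The deposited values are signal intensity on a linear scale; on every array the mean over all probe sets, after leaving out the lowest and highest 2%, came to 500.04 to 500.08. The table holds 22810 probe sets, of which 64 are controls. Of the 22746 Arabidopsis probe sets, 13513 name exactly 1 gene in the platform annotation used here, 503 name several, and 8730 carry no name and were kept in every count without one. Of the 13513, 13436 matched a locus in the TAIR10.1 gene table, which was used for names only. No coordinates are printed because the build behind the probe sets is not given in the sources used here. Raw scans and detection calls were not analysed here.

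Array medians ranged from 100.0126 to 185.3585, a ratio of 1.85. By the rule fixed before the data were examined, a ratio above 1.5 called for median centring, so the main values are log2(signal + 30.2143), where the offset is the 25th percentile of all values, centred on each array's median over the tested probe sets. A probe set was tested if it exceeded its array's 40th percentile on at least 2 of the 16 arrays, which kept 19475 and left out 3271. Each array's background bound is the 95th percentile of its 27 Bacillus control probe sets, a measure chosen after seeing the data. It ranged from 31.1 to 161, and 44.7% to 71.1% of Arabidopsis probe sets lay above it. A fold is given as "at least" where every low-side array lay at or under its bound, and is then computed against the bound. Where only some low-side arrays did, a difference printed is that of the model and no exact size. The 3' to 5' signal ratio of the GAPDH control ranged from 3.49 to 24.7, that of ubiquitin from 5.18 to 11.4 and that of actin from 6.11 to 40.8. The 100 brightest probe sets took 12.2% to 22.7% of the signal.

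One linear model with 7 group means was fitted across all tested probe sets with limma 3.58.1 (eBayes with an intensity trend) in R 4.3.3. Tests were two-sided with Benjamini-Hochberg adjustment at 0.05. The 6 comparisons were the embryo proper against the mean of 3 endosperm regions, endosperm against seed coat regions, chalazal against other endosperm, micropylar against peripheral endosperm, chalazal seed coat against seed coat, and whole seeds against the mean of the 6 compartments. A probe set counted as enriched in a compartment by the largest of its 5 one-sided p-values against each other compartment, adjusted in the same way. Every log2 difference is the first-named side minus the other, with the model's SE.

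Named genes follow a rule fixed before the data were examined. For each comparison they are the 10 probe sets with the largest difference in each direction that pass the threshold, name 1 gene and have no overlap between the arrays of either side. Added to them are up to 4 genes per list with the smallest p, and for enriched sets the 8 with the largest gap to the next compartment plus list members. Not all are printed. The gene lists, fixed at the same time, were embryo patterning and meristem, seed maturation and storage, photosynthesis, endosperm regulators, cytokinin, gibberellin metabolism, abscisic acid metabolism, auxin synthesis and transport, flavonoid and proanthocyanidin, seed coat epidermis and mucilage, phloem, xylem, nutrient transport, mitosis, DNA replication, fatty acid and oil synthesis, DNA methylation and small RNA, heat shock, and developmental cell death. The lists were tested with camera in limma at a preset inter-gene correlation of 0.01, on the brightest probe set per gene, where at least 5 genes were tested; p-values were adjusted over lists and comparisons. A set p with no tool named is from this test; fry, an alternative, asks whether the genes of a set move on balance 1 way, not whether they move more than other genes. Only 4 lists reached 5 genes, because 51 of 393 members were named. In addition, 23 gene families defined by symbol patterns were written down after the values were at hand but before differences were computed, and adjusted as a separate group. The results of 1 of these families, and of its genes in the lists, are not reported here. All plastid family members lie on the plastid genome in the gene table, while the 15 mitochondrial genes were recognised by platform symbol alone.

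The pipeline was tested on simulated data with 200 changed genes per run and the spread of each group as measured. At a true log2 difference of 4 the 6 comparisons recovered 83.3% to 100% of changed genes and at 2 they recovered 9% to 68.7%. False calls were 0% to 3.4% except 15.7% for the chalazal endosperm comparison (9.2% with array weights). In runs with an equal spread in all groups false calls of the 6 comparisons were 1.5% to 8.5%. Enriched sets at a difference of 4 were recovered at 68.2% to 87.9%, and at a difference of 2 at 0% to 16.4%. Their false calls were 0, but a call needs a probe set higher than in every other compartment, which equal means rarely allow. Probe sets raised alike in 2 compartments were not simulated. The 0 thus does not show how often such probe sets are called enriched by mistake. The list test found the 1 shifted list of 20, without which the pipeline would have stopped, and called 0 of the 114 pairs of the other 19 lists with a comparison. Simulated genes varied independently, so this does not show how the test acts on correlated genes. The estimated correlation of the photosynthesis list was 0.387.

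Alternatives were quantile normalisation, offsets of 1 and of the 40th percentile (79.4452), no filter or a 60th percentile filter, no variance trend, array weights, a replicate block, only the groups compared, camera with estimated correlation, all probe sets per gene, fry, and leaving out each array. Added after seeing the data were the deposited scaling without centring, weights per group, and the chalazal endosperm with array 3 alone. Python 3.11.15 with pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9 prepared tables and figures.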

Results

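Transcript levels were measured on 16 Affymetrix ATH1 arrays hybridised with amplified RNA from Arabidopsis Ws-0 seeds holding a heart-shaped embryo. Laser capture microdissection, which cuts chosen regions out of tissue sections under a microscope, gave 6 compartments and also the whole seeds. The embryo proper, the micropylar endosperm (around the embryo), the peripheral endosperm (lining the seed cavity) and the seed coat had 2 arrays each. The chalazal endosperm and the chalazal seed coat, which lie at the end of the seed where the maternal supply enters, had 3 arrays each. Whole seeds had 2 arrays. Each array gave 1 signal value for each of 22746 Arabidopsis probe sets, of which 19475 were bright enough to be tested. Of these, 11274 name exactly 1 gene, and 7784 carry no gene name in the annotation used here. The number of arrays per group limits the precision of every value. The p-values measure only the spread between these arrays, which the labels call biological replicates without saying which plants or sections each came from.

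The chalazal endosperm arrays stood apart from every other group, in technical measures as well. Across the tested probe sets, which are not independent replicates, Pearson correlations between chalazal endosperm arrays and arrays of other groups lay between 0.435 and 0.656. Within the chalazal endosperm they lay between 0.822 and 0.856. The embryo proper and the micropylar endosperm correlated at a mean of 0.860, the micropylar and peripheral endosperm at 0.878, and whole seeds and seed coat at 0.853. The first principal component, with 32.2% of the variance, separated the chalazal endosperm, and the second, with 26.1%, separated both seed coat regions from the embryo and endosperm regions. The median SD between replicates was 0.70 on the log2 scale in the chalazal endosperm and 0.64 in the chalazal seed coat, against 0.28 to 0.43 in the other groups. The first 2 values rest on 3 arrays and the others on 2. A median SD runs lower with 2 arrays, so the contrast is overstated. Signal of the cre hybridisation controls, which are added to each sample in a set amount, averaged 242806 ± 42663 (SD, n = 3) in the chalazal endosperm and 214216 ± 24560.4 (SD, n = 3) in the chalazal seed coat. The cre mean was 161174 in whole seeds (n = 2), 131741 in the seed coat (n = 2) and 101393, 99641 and 105147 in the embryo proper, micropylar and peripheral endosperm (n = 2 each). In the chalazal endosperm the 100 brightest probe sets took 21.2% of the signal on average, against 12.6% to 16.1% in the other groups, and the highest signal averaged 182747 against 40659 to 94189. Its mean control background of 108 was the highest and the 53.2% of probe sets above it the lowest of the 7 groups.

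**Figure D1:**
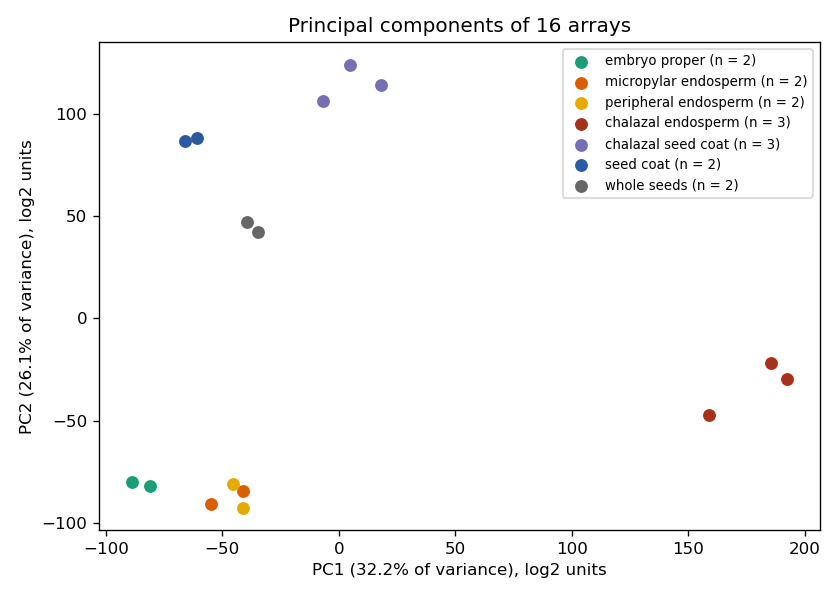
Principal components of the 16 arrays, computed from the median-centred log2 signal of the tested probe sets. The x axis is the first component (32.2% of the variance) and the y axis the second (26.1%), both in log2 units; each point is 1 array, coloured by group, and the 3 chalazal endosperm arrays lie apart from the other 13 along x.

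The comparison of the embryo proper (n = 2) with the mean of the 3 endosperm regions (n = 7) addressed which transcripts separate both products of fertilisation. Of 6 tested genes of the embryo patterning and meristem list, 4 were higher in the embryo proper, over all genes and when adjusted over the list alone, and CLV3 and YAB3 did not pass the test. PHV (AT1G30490), a homeodomain regulator of adaxial fate, was higher by a log2 difference of 3.28 ± 0.54 (SE; adjusted p = 1.11e-04), and the epidermal receptor kinase CR4 (AT3G59420) by 3.05 ± 0.57 (adjusted p = 4.98e-04). The vascular regulator LHW (AT2G27230) was higher by 2.96 ± 0.61, and BBM (AT5G17430), an AP2-domain regulator of embryo identity, by 2.22 ± 0.56. Large differences in the same direction were those of AT3G15720 (4.63 ± 0.56), the glutathione S-transferase GSTU27 (4.63 ± 0.64), the tetraspanin TET15 (4.61 ± 0.62), AT3G51670 (4.58), AT1G29270 (4.53), AT1G71691 (4.38), AT3G24250 (4.36), AT1G78170 (4.33), AT3G52920 (4.21) and the expansin EXPA15 (4.18). AT2G39640 (-6.26 ± 0.43, adjusted p = 2.10e-10) and AT5G40155 (-5.59 ± 0.48) were lower in the embryo proper. AT3G26590 was at least 18.5-fold lower, AT3G42830 at least 20-fold, AT5G63740 at least 22.7-fold and AT5G59845 at least 20.9-fold, since both embryo arrays were at or under the control background.

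The embryo list moved up as a set (adjusted p = 4.13e-04), with adjusted p = 0.0664 with an estimated correlation. The endosperm regulator list fell (adjusted p = 0.00750, and adjusted p = 0.0664 with an estimated correlation). Of its 6 tested genes 3 were lower over all genes and 4 when adjusted over the list alone, and not all of these calls held without either embryo proper array. Among 5 tested genes of the cell death list, the vacuolar processing enzyme genes DELTA-VPE (-2.19 ± 0.43) and GAMMA-VPE (-1.73 ± 0.35) were lower, as was ALPHA-VPE (-1.62 ± 0.52, adjusted p = 0.0370), and the same 3 counted as lower when adjusted over the list alone. The list as a set had adjusted p = 0.253. DFR (AT5G42800), a dihydroflavonol reductase of the flavonoid pathway, was lower by -3.17 ± 0.44 (adjusted p = 1.38e-05). The flavonoid list, of which 1 of 3 tested genes fell (2 adjusted over the list alone), serves here as a marker of seed coat. Its median signal relative to the 16-array mean was -3.49 and -3.08 in the embryo arrays and 0.47 and -0.59 in the peripheral endosperm arrays. Also higher was the spindle checkpoint gene BUBR1 (1.69 ± 0.50, adjusted p = 0.0236), 1 of 3 tested mitosis genes. PRL (1.36 ± 0.46, adjusted p = 0.0464), a subunit of the replicative helicase and the lone tested DNA replication gene, was higher too. Both passed when adjusted over their list alone. PRL averaged 11.524 in the embryo proper and 11.275, 10.644 and 8.567 in the micropylar, peripheral and chalazal endosperm. In the same order BUBR1 averaged 9.716, 8.743, 8.824 and 6.526, with every chalazal endosperm array at or under the control background. For both genes, differences from the micropylar and peripheral endosperm alone were not tested.

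Families were defined by gene symbol after the values were at hand but before any difference was computed. Of 14 IQD genes, which encode calmodulin-binding proteins, 5 were higher, among them IQD31 (3.30 ± 0.48) and iqd32 (2.97 ± 0.59); the set had adjusted p = 9.95e-06, and adjusted p = 0.156 with an estimated correlation. Among 43 plastid-encoded photosynthesis genes 25 were lower, with a median of -1.29 (set adjusted p = 2.44e-10; adjusted p = 0.570 with an estimated correlation). Without centring 17 were lower (median -1.02), and with quantile normalisation 13 (median -0.80).

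In all, 1052 probe sets were higher and 1627 lower in the embryo proper (limma, adjusted over all tested probe sets). The median difference over all tested probe sets was -0.29, and without centring of the arrays it was -0.01, with 1716 higher and 1110 lower; quantile normalisation gave 1344 and 1105. Array weights gave 2549 and 4088, and an offset of 1 before taking logs gave 625 higher. Without embryo proper replicate 1 the counts were 254 and 525, and without replicate 2 they were 323 and 616, where the lone remaining array is assumed to vary like the other groups. Without embryo proper replicate 1 the adjusted p rose to 0.134 for BBM, 0.128 for ALPHA-VPE, 0.113 for BUBR1 and 0.165 for PRL. Without replicate 2 it rose to 0.101 for BBM, 0.0534 for LHW, 0.401 for ALPHA-VPE, 0.341 for BUBR1 and 0.409 for PRL. PRL (up to 0.103) also lost its call when any 1 array of the micropylar endosperm, the peripheral endosperm, the seed coat or the whole seeds was left out. ALPHA-VPE lost its call without micropylar replicate 2 (0.0635) or peripheral replicate 1 (0.0841), and BUBR1 without peripheral replicate 2 (0.0618). Without centring ALPHA-VPE had adjusted p = 0.0909, and with quantile normalisation 0.0697.

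The comparison of the 3 endosperm regions (n = 7) with both seed coat regions (n = 5) addressed which transcripts separate filial from maternal tissue around the embryo. All 3 tested mitosis genes were higher in endosperm, over all genes and when adjusted over the list alone; a list of this size had no set test. The Aurora kinase genes AUR1 and AUR2 were higher by 4.86 ± 0.41 (adjusted p = 3.41e-10) and 4.07 ± 0.43, and the spindle checkpoint gene BUBR1 was at least 2.26-fold higher (adjusted p = 2.45e-05), since all 5 seed coat arrays were at or under the control background. BUBR1 was at or under that background on every chalazal endosperm array too. The gene of the chromosome-binding protein 3xHMG-box2 (AT4G23800) was higher by 5.68 ± 0.37 (adjusted p = 3.08e-12). Of 3 tested flavonoid genes 2 were lower, with as many when adjusted over the list alone, and UGT80B1 did not pass the test. Lower were BAN (AT1G61720), an anthocyanidin reductase of proanthocyanidin synthesis, by -5.25 ± 0.40 (adjusted p = 6.40e-11), and DFR by -4.53 ± 0.33 (adjusted p = 2.01e-11). Other large differences in favour of endosperm were those of AT2G30810 (5.52), AT3G44050 (5.49), AT5G54220 (5.34), AT5G60930 (5.26), AT5G47550 (5.11), the sugar transporter gene SWEET8 (5.11 ± 0.35), AT2G02515 (5.02) and AT3G10780 (5.01). In favour of seed coat they were those of AT4G12890 (-6.87), AT1G62480 (-6.80), AT2G16890 (-6.42), AT1G26930 (-6.40), GILT (-6.25), the zinc transporter family gene ZIP6 (-5.97), TBL38 (-5.91), AT5G60140 (-5.77), AT5G22460 (-5.70) and AT5G40140 (-5.68).

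All 5 tested nuclear photosynthesis genes were higher in the mean of the endosperm regions, over all genes and when adjusted over the list alone. Among them were the photosystem I subunit genes PSAE-1 (4.50 ± 0.35) and PSAN (3.72 ± 0.40). The antenna genes LHCB4.2 (3.07 ± 0.37) and LHCB4.1 (2.64 ± 0.33) were others. For these named genes the chalazal endosperm mean also lay above both seed coat means. RCA, the Rubisco activase gene, averaged 7.716 in the chalazal endosperm, against 8.652 in the chalazal seed coat and 7.699 in the seed coat. As a set the list had adjusted p = 1.44e-04, and adjusted p = 0.0960 with an estimated correlation. Plastid-encoded genes were higher too: 37 of 43 for photosynthesis (median 1.29) and 19 of 19 for plastid gene expression (median 1.75), with set adjusted p = 2.37e-10 and 3.14e-09. With an estimated correlation these became adjusted p = 0.570 and adjusted p = 0.534. Mitochondria-encoded genes, recognised by symbol alone, were lower, 9 of 15, with a median of -0.91; cox1 fell by 0.99 ± 0.22 and nad5 by 0.91 ± 0.20. Their set adjusted p was 0.00779, and adjusted p = 0.570 with an estimated correlation. Of 6 endosperm regulators 4 were higher, with as many when adjusted over the list alone, and the list's adjusted p was 0.0536; not all of these calls held without seed coat replicate 1.

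Of the cell death list, with adjusted p = 0.239 as a set, ALPHA-VPE was higher (2.74 ± 0.39). BETA-VPE (-3.71 ± 0.34), GAMMA-VPE (-1.32 ± 0.26) and DELTA-VPE (-1.0 ± 0.32) were lower. Adjusted over the list alone the split of 1 and 3 was the same. GAMMA-VPE averaged 11.037 in the micropylar and 10.909 in the peripheral endosperm, below both seed coat regions. Its chalazal endosperm mean of 13.274 was not below the 13.123 of the chalazal seed coat and 13.005 of the seed coat. The mean log2 signal of DELTA-VPE was 14.42 in the seed coat. In the chalazal seed coat it was 7.95, below the 8.76 to 11.11 of the endosperm regions. DELTA-VPE had adjusted p = 0.0160, which rose above the threshold without peripheral endosperm replicate 2 (0.0770), micropylar endosperm replicate 2 (0.0515), chalazal seed coat replicate 2 (0.0533), seed coat replicate 1 (0.0615) and seed coat replicate 2 (0.0629). Of 3 tested seed coat epidermis and mucilage genes, the subtilase gene ARA12 (-3.92 ± 0.45) was lower, AT3G10320 at least 1.54-fold lower (all 7 endosperm arrays at or under the control background) and AT2G22900 (1.54 ± 0.37) higher, with the same counts when adjusted over the list alone. AT3G10320 was also at or under that background on both seed coat arrays, and above it on all 3 chalazal seed coat arrays. For this list, a marker of seed coat, the medians of the 3 chalazal seed coat arrays were -0.31, -0.81 and 2.30 relative to the 16-array mean. The auxin synthesis gene YUC6 (-3.02 ± 0.39), 1 of 4 tested in its list, and LHW (-2.17 ± 0.45), 1 of 6 embryo list genes, were lower. The oleosin gene OLEO3 (4.14 ± 0.50), 1 of 3 seed maturation genes, SAG29 (1.93 ± 0.42), a SWEET sugar transporter and 1 of 2 nutrient transport genes, the acyl-ACP thioesterase gene FaTA (1.60 ± 0.33), 1 of 2 oil synthesis genes, and PRL (1.26 ± 0.34) were higher. For these 6 lists the counts adjusted over the list alone were the same. Not every region followed these means. In the chalazal endosperm PRL averaged 8.567, against 8.935 in the chalazal seed coat and 8.87 in the seed coat. In the same order FaTA had 9.498, 9.429 and 9.525, and AT2G22900 had 7.879, 7.614 and 9.315. SAG29 had 6.498, 6.684 and 5.454, with every chalazal endosperm array at or under the control background. LHW averaged 9.351 in the micropylar endosperm, against 8.406 in the seed coat.

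In all, 3852 probe sets were higher and 2996 lower in endosperm. The median over all tested probe sets was 0.19; without centring it was -0.02, with 2886 higher and 3651 lower, and quantile normalisation gave 3254 and 3243. Which direction held more probe sets turned with the scaling, while no gene named above for this comparison changed sign under either alternative.

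**Figure D2:**
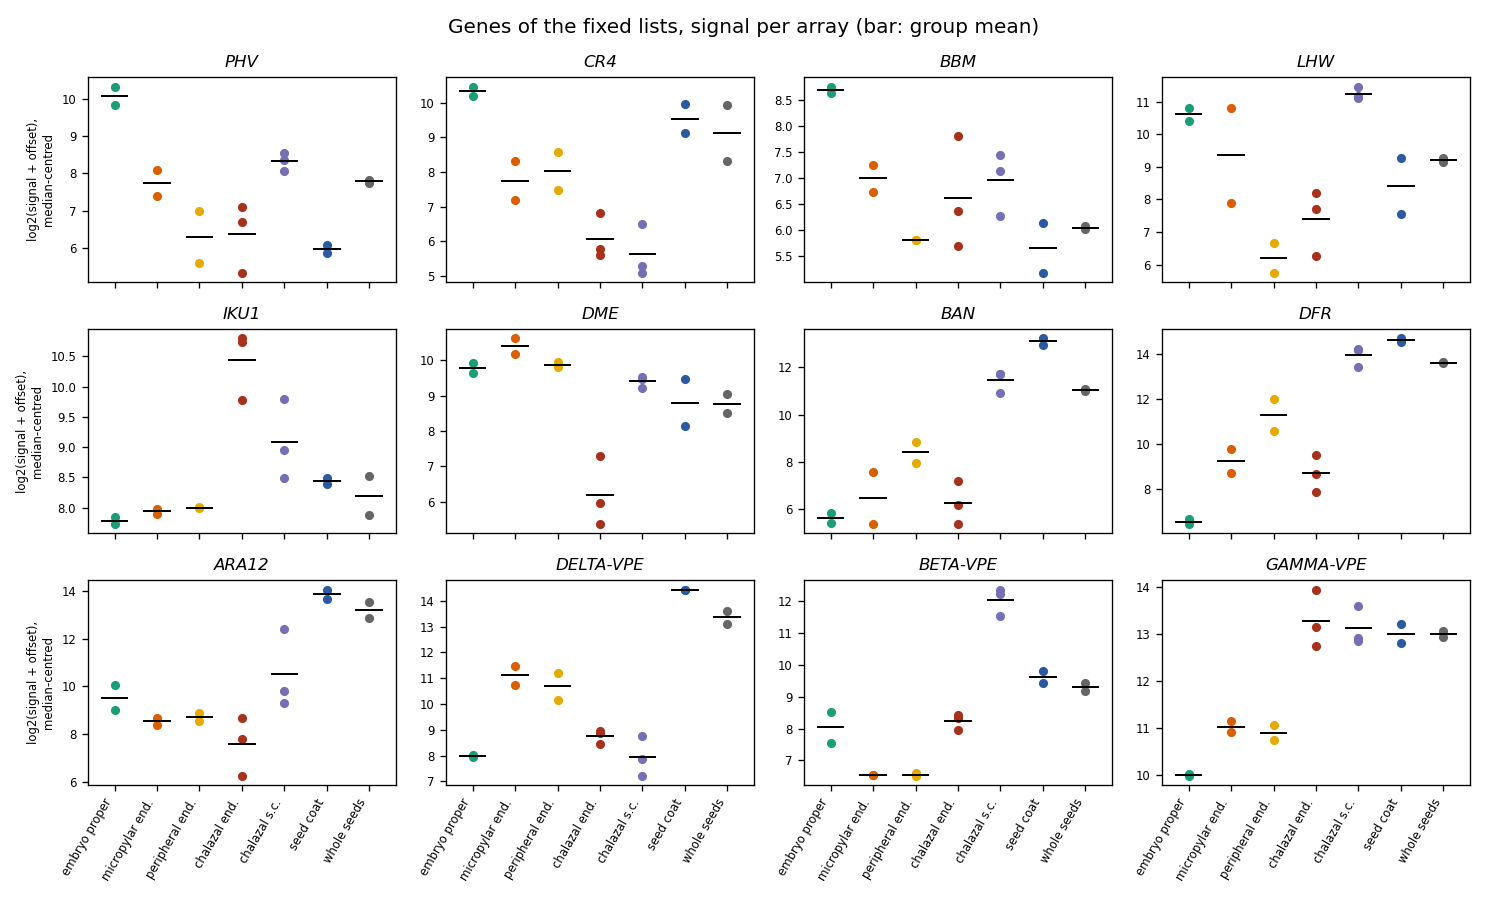
Signal of 12 genes of the fixed lists, 1 panel per gene, as median-centred log2(signal + offset) on the y axis (each panel has its own range) by group on the x axis; points are arrays and bars group means. DME averages 6.20 in the chalazal endosperm, where 2 of 3 arrays are at or under the control background, against 8.81 or more in the other compartments.

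The comparison of the chalazal endosperm (n = 3) with the mean of the micropylar and peripheral endosperm (n = 4) addressed how the chalazal pole differs from the rest of the endosperm. AT2G15325 was at least 473-fold higher, AT4G35985 at least 400.1-fold, AT2G20170 at least 397-fold, CYP79A2 (AT5G05260), a cytochrome P450 that turns phenylalanine into its aldoxime, at least 351-fold, AT4G15040 at least 339-fold and AT4G37950 at least 298-fold, each from low-side arrays at or under the control background. AT1G07690 (9.73 ± 0.51, adjusted p = 5.19e-14), AT3G13370 (9.58), the ubiquitin-conjugating enzyme gene UBC31 (9.07 ± 0.47) and AT2G44250 (9.02) were higher as well. AT1G67820 (-6.87 ± 0.46, adjusted p = 2.84e-12), the defensin-like genes PDF2.1 (-5.99 ± 0.51) and LCR69 (-5.75 ± 0.53), AT5G24490 (-5.86), AT5G55520 (-5.56), AT3G57930 (-5.45) and AT1G04645 (-5.42) were lower. The endoglucanase gene GH9C1 was at least 23.9-fold lower, AT5G17760 at least 16.6-fold and AT4G36700 at least 13.3-fold.

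The endosperm regulator list rose in the chalazal endosperm (adjusted p = 0.00553; adjusted p = 0.0664 with an estimated correlation), with 5 of 6 genes higher both over all genes and when adjusted over the list alone. Among them IKU1, a promoter of endosperm growth, was higher by 2.47 ± 0.45. All 9 tested ATG8 genes, whose products build autophagosomes, were higher (median 2.99, and between 2.34 and 2.99 under the 3 scalings; without centring 8 of 9 passed). ATG8D (3.56 ± 0.43) and ATG8F (3.07 ± 0.31) were among them, and ATG8H was at least 9.04-fold higher, since all 4 low-side arrays were at or under the control background. The set had adjusted p = 8.48e-05, and adjusted p = 0.156 with an estimated correlation. The adjacent chalazal seed coat had higher mean signal than the chalazal endosperm for ATG8B (11.62 against 8.55), APG8H (11.78 against 11.61) and ATG8E (10.52 against 10.46), and 2 of 9, ATG8D and ATG8F, were enriched in the chalazal endosperm over every other compartment. Nuclear photosynthesis genes fell, 3 of 5 over all genes (5 without centring) and 5 when adjusted over the list alone (adjusted p = 0.00860; adjusted p = 0.214 with an estimated correlation): PSAN by -2.90 ± 0.51, RCA, the Rubisco activase gene, by -2.56 ± 0.53, and PSAE-1 by -2.12 ± 0.45. Plastid-encoded photosynthesis genes had a positive median of 0.84 (15 of 43 higher, set adjusted p = 0.0458, adjusted p = 0.810 with an estimated correlation), which turned to -0.07 under quantile normalisation; 8 were higher without centring and 0 with quantile normalisation. That set also lost its call without micropylar endosperm replicate 2 (adjusted p = 0.273), peripheral endosperm replicate 1 (0.0945), chalazal endosperm replicate 1 (0.169), chalazal endosperm replicate 2 (0.344), chalazal seed coat replicate 2 (0.0536), seed coat replicate 1 (0.0506) and seed coat replicate 2 (0.0529).

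DME, the DNA glycosylase that removes methylated cytosine and the lone tested member of its list, was lower (adjusted p = 1.90e-07). It lay at or under the control background on 2 of 3 chalazal arrays, so no exact size is given, and its 2 other probe sets, also lower, lay at or under the control background on all 3 chalazal endosperm arrays. Of 5 cell death genes, with adjusted p = 0.791 as a set, GAMMA-VPE (2.30 ± 0.33) and BETA-VPE (1.69 ± 0.43) were higher and DELTA-VPE (-2.13 ± 0.41) and, with 2 of 3 chalazal arrays at or under the control background, scpl48 lower, and adjusted over the list alone the counts were the same. BZIP53 (2.26 ± 0.41) was higher and OLEO3 (-3.28 ± 0.64) lower among 3 seed maturation genes. Of 4 auxin genes YUC2 was at least 2.14-fold higher (adjusted p = 0.00263) and YUC6 at least 1.07-fold (adjusted p = 0.0429), both from low-side arrays at or under the control background. For YUC6 1 of 3 chalazal arrays lay above it, and its adjusted p rose, to at most 0.129, without micropylar endosperm replicate 1 and without any 1 array of the embryo proper, the peripheral endosperm or the chalazal endosperm. FaTA (-2.37 ± 0.42) was lower and FATB (1.14 ± 0.44, adjusted p = 0.0443) higher, and FATB rose to at most 0.253 without chalazal endosperm replicate 3, and it lost its call too without replicate 1 or any 1 array of the embryo proper, micropylar endosperm, peripheral endosperm or whole seeds. Without centring YUC6 had 0.110 and FATB 0.127, and with quantile normalisation 0.0630 and 0.0838. PRL (-2.39 ± 0.44) and AT2G22900 (-3.19 ± 0.47), 1 of 3 mucilage genes, were lower. BUBR1, 1 of 3 mitosis genes, was at least 2.67-fold lower, SAG29, 1 of 2 nutrient transport genes, at least 2.60-fold and CR4, 1 of 6 embryo list genes, at least 1.43-fold, with all 3 chalazal arrays at or under the control background. SAG29 averaged 10.432 in the micropylar and 7.059 in the peripheral endosperm. The bounds of the chalazal arrays lay at 7.75, 7.521 and 6.835 on the same scale. The fold of SAG29 thus rests on the micropylar endosperm. CR4 had adjusted p = 0.0555 without peripheral endosperm replicate 1. DFR fell by 1.57 ± 0.42, 1 of 3 flavonoid genes (2 adjusted over the list alone). For the other lists of this paragraph the counts adjusted over the list alone were the same.

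In all, 3812 probe sets were higher and 3509 lower in the chalazal endosperm. The median over all tested probe sets was 0.24; without centring it was -0.03, with 2776 higher and 4269 lower, and quantile normalisation gave 3211 and 3778. With array 3 alone, whose control background was the lowest of the 3, the counts were 2291 and 1933, a choice made after seeing the data; YUC2 (adjusted p = 0.183), YUC6 (0.133), CR4 (0.329) and DFR (0.340) then lost their calls. On simulated data with the spread of each group as measured, this comparison gave 15.7% false calls at the adjusted p threshold of 0.05, which is an excess. That figure rests on 18 false calls in a run where few probe sets were changed, while 37.59% of those tested were called here. It therefore does not give the share of false calls among the real ones, which was not estimated.

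**Figure D3:**
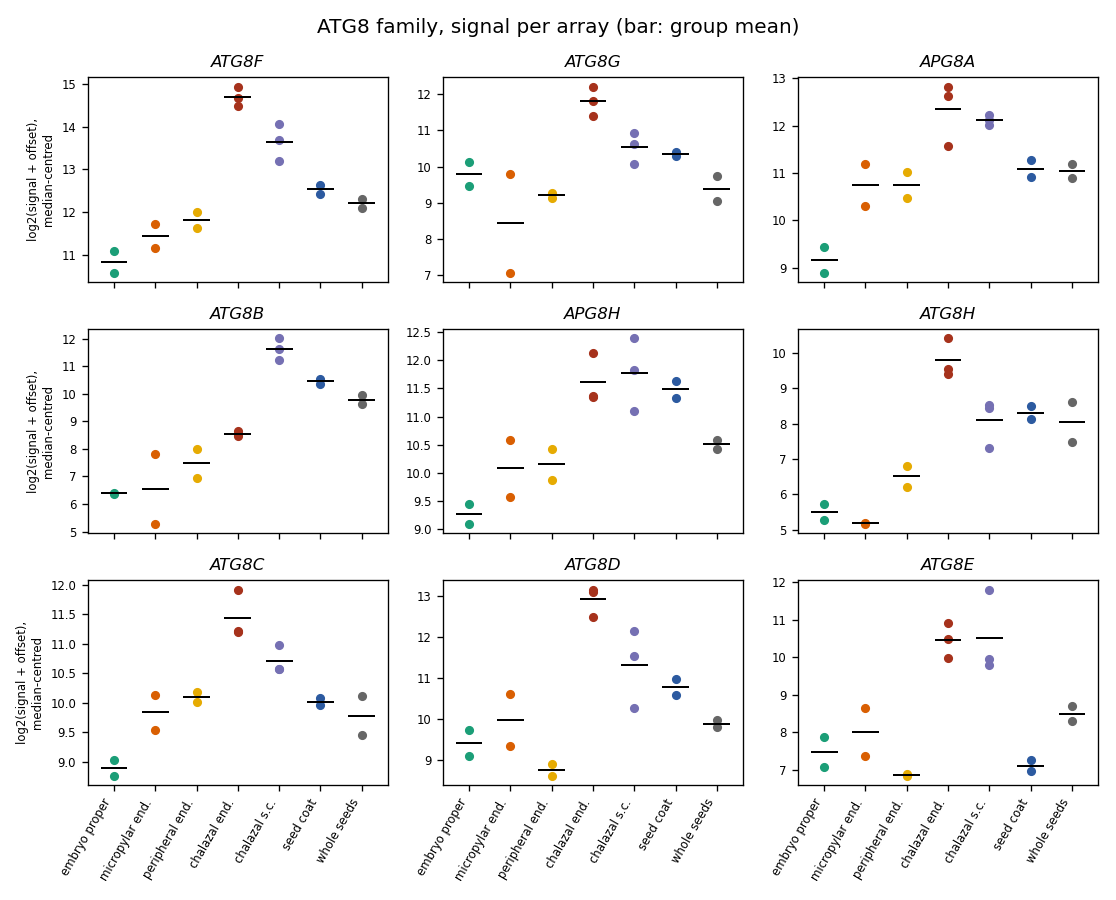
Signal of the 9 tested ATG8 family genes, 1 panel per gene, as median-centred log2(signal + offset) on the y axis (each panel has its own range) by group on the x axis; points are arrays and bars group means. Every gene is higher in the chalazal endosperm than in the micropylar and peripheral endosperm, under the scaling drawn and under both others. Log2 differences run from 1.48 (ATG8C) to 3.56 (ATG8D), and ATG8H, at or under the control background on the 4 low-side arrays, is at least 9.04-fold higher.

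The comparison of the micropylar (n = 2) with the peripheral endosperm (n = 2) addressed how the endosperm around the embryo differs from that lining the cavity. AT3G24250 (5.98 ± 0.82, adjusted p = 2.42e-04), AT1G71250 (5.46 ± 0.67, adjusted p = 1.57e-04) and AT1G09370 (4.58 ± 0.68) were higher in the micropylar endosperm, and AT5G66670 was at least 13.9-fold higher. AT5G22580 was at least 10.5-fold lower (adjusted p = 6.64e-04). These 5 held without any single array. The carboxypeptidase gene scpl48 (3.95 ± 0.65), 1 of 5 cell death genes (set adjusted p = 0.137), was higher, with adjusted p = 0.0560 without micropylar endosperm replicate 1 and 0.0997 without peripheral endosperm replicate 2. The sugar transporter gene SAG29 (3.37 ± 0.71), 1 of 2 nutrient transport genes, was higher, with adjusted p of 0.268, 0.151 and 0.162 without micropylar endosperm replicate 1, peripheral endosperm replicate 1 and peripheral endosperm replicate 2. The subtilase gene SBT1.3 (4.57 ± 0.77) had adjusted p of 0.162 and 0.107 without micropylar endosperm replicate 1 and peripheral endosperm replicate 2. HYH, a bZIP regulator of light responses, was lower (-3.60 ± 0.76), with 0.251, 0.103 and 0.245 without micropylar replicate 1, peripheral replicate 1 and peripheral replicate 2. HPR, the hydroxypyruvate reductase gene of photorespiration, was lower (-2.99 ± 0.66), with 0.228, 0.162 and 0.275 without micropylar replicate 2, peripheral replicate 1 and peripheral replicate 2.

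The embryo list moved up as a set (adjusted p = 0.00860; adjusted p = 0.132 with an estimated correlation), with 1 of 6 genes, LHW (3.14 ± 0.75), past the threshold over all genes and over the list alone. For 3 of the 6 genes every low-side array was at or under the control background. With these set at the bound the list's median difference was 0.22 in place of 1.12. Its array medians were 0.57 and -0.41 in the micropylar endosperm, -0.49 and -0.80 in the peripheral endosperm, and 1.75 and 1.89 in the embryo proper. Without micropylar replicate 1 the list had adjusted p = 0.270 and LHW 0.955; without peripheral replicate 2 they had 0.129 and 0.540, and LHW 0.118 without peripheral replicate 1. LHW also lost its call without whole seeds replicate 1 (0.0521) or 2 (0.0517), and with quantile normalisation (0.0645). Photosynthesis moved down as a set (adjusted p = 0.00450; adjusted p = 0.179 with an estimated correlation), with 0 of 5 genes past the threshold in limma and 1 when adjusted over the list alone; without micropylar replicate 2 its adjusted p was 0.123. The endosperm regulator list had 0 of 6 genes past the threshold and adjusted p = 0.552. DFR was at -2.03 ± 0.55 (adjusted p = 0.0724), and 2 of 3 flavonoid genes were lower when adjusted over the list alone. The response regulator gene RR16, 1 of 2 cytokinin genes (2 adjusted over the list alone), was at least 2.34-fold higher (adjusted p = 0.0236), from peripheral arrays at or under the control background, with adjusted p of 0.302, 0.0607, 0.196 and 0.293 as each of the 4 arrays was left out in turn. For these cell death and nutrient transport genes the counts adjusted over the list alone were the same.

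In all, 159 probe sets were higher and 38 lower in the micropylar endosperm. Array weights gave 321 and 109, an offset of 1 gave 55 and 9, and a fit of only the groups compared gave 52 and 9; with chalazal endosperm array 3 alone 58 were lower. Without micropylar replicate 1 the counts were 34 and 7, without peripheral replicate 1 they were 53 and 2, and without peripheral replicate 2 they were 18 and 2, where the lone array is assumed to vary like the other groups.

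The comparison of the chalazal seed coat (n = 3) with the seed coat (n = 2) addressed how the maternal tissue at the supply end differs from the rest of the seed coat. AT3G10590 was at least 359-fold higher, AT4G33550 at least 182-fold, AT5G24580 at least 176-fold, AT1G43910 at least 156-fold, AT3G14780 at least 140.0-fold, AT4G22050 at least 140.2-fold, AT4G22400 at least 126-fold, AT5G40980 at least 110-fold and AT2G38800 at least 101-fold in the chalazal seed coat. The defensin-like gene LCR68 (8.09 ± 0.67, adjusted p = 1.04e-09) was higher as well, and the sugar transporter gene SWEET10 at least 94.6-fold. The thionin gene THI2.1 (-9.11 ± 0.73, adjusted p = 7.89e-10) was lower, as were AT1G11590 (-7.69), AT5G47350 (-7.31), AT1G49800 (-7.13), AT1G29660 (-7.07), AT3G05600 (-6.58), AT5G60630 (-6.51), DELTA-VPE (-6.48 ± 0.49), AT4G03930 (-6.36) and AT1G12010, which was at least 53.4-fold lower.

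None of the 4 fixed lists with 5 or more tested genes passed the threshold in camera; at an unadjusted p under 0.05 the count was 0, and fry called 2 of them. Of 6 embryo list genes (adjusted p = 0.537) LHW was higher (2.84 ± 0.69), PHV at least 2.96-fold higher and CR4 at least 6.0-fold lower, as also when adjusted over the list alone. LHW had adjusted p = 0.233 without seed coat replicate 2, and PHV 0.112 and 0.0786 without seed coat replicates 1 and 2. BETA-VPE (2.40 ± 0.51) was higher and DELTA-VPE lower among 5 cell death genes (adjusted p = 0.239), with 1 and 2 when adjusted over the list alone. ARA12 (-3.34 ± 0.69) was lower, AT3G10320 at least 3.50-fold higher and AT2G22900 (-1.7 ± 0.56, adjusted p = 0.0495) lower in the mucilage list. AT3G10320 had 0.0659 and 0.144 without seed coat replicates 1 and 2, and AT2G22900 lost its call when 1 array of the embryo proper, peripheral endosperm, seed coat or whole seeds, or chalazal seed coat replicate 1 or 3, was left out, with at most 0.278 without seed coat replicate 1. It had 0.0682 without centring and 0.0607 with quantile normalisation. Mucilage list counts were the same when adjusted over the list alone. Of 6 endosperm regulators (adjusted p = 0.185) 1 was higher, a call that did not hold without seed coat replicate 1 or 2. RR16 was at least 2.60-fold higher (adjusted p = 0.0131), with 0.0507, 0.0597 and 0.174 without chalazal seed coat replicate 1, seed coat replicate 1 and seed coat replicate 2. Both counts, 1 of 6 and 1 of 2 cytokinin genes, were the same when adjusted over the list alone. Over the list alone 1 auxin gene, YUC6 (1.7 ± 0.59, adjusted p = 0.0639 over all genes), was higher and 1 flavonoid gene, BAN (-1.63 ± 0.62, adjusted p = 0.0923), lower. The photosynthesis list had 0 of 5 genes past the threshold, 1 lower adjusted over the list alone, and adjusted p = 0.385. Phloem genes had 0 of 2 past the threshold in every comparison, with OPS higher here when adjusted over the list alone (at least 2.58-fold, adjusted p = 0.0784 over all genes). Of 23 serine carboxypeptidase-like genes 7 were lower and 1 higher (set adjusted p = 0.00993; adjusted p = 0.156 with an estimated correlation), among them scpl20 (-5.73 ± 0.55) and scpl35 (-3.83 ± 0.75). Of 16 expansins, proteins that loosen cell walls, 4 were higher, among them EXLA3 (at least 7.12-fold) and EXLA2 (2.53 ± 0.71), with set adjusted p = 0.0177, and adjusted p = 0.352 with an estimated correlation; without chalazal seed coat replicate 2 and seed coat replicate 2 it was 0.0520 and 0.0529.

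In all, 1014 probe sets were higher and 1098 lower in the chalazal seed coat, and with an offset of 1 the lower count was 690. Without seed coat replicate 1 the counts were 553 and 538, and without replicate 2 they were 537 and 437, where the lone array is assumed to vary like the other groups.

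Whole seeds (n = 2) were compared with the mean of the 6 compartments (n = 14). Among genes of the fixed lists, 4 were higher in whole seeds: ARA12 by 3.42 ± 0.57 (adjusted p = 3.53e-04), DELTA-VPE by 3.21 ± 0.41 (adjusted p = 1.20e-05), DFR by 2.89 ± 0.41 (adjusted p = 5.58e-05) and BAN by 2.49 ± 0.51 (adjusted p = 0.00337). OCT1 (4.39 ± 0.56), an organic cation transporter gene, MT1C (3.57 ± 0.48), a metallothionein gene, AT5G63180 (3.51 ± 0.48) and AT4G33660 (2.67 ± 0.50) were higher on both whole seed arrays than on every compartment array. AT3G60980 was at least 3.33-fold lower (adjusted p = 0.00258), AT3G26050 at least 2.80-fold and AT1G02870 at least 4.2-fold. BAN had adjusted p of 0.116 and 0.124 without whole seeds replicates 1 and 2, ARA12 0.0738 without replicate 1, AT4G33660 0.134 without replicate 2, AT3G60980 0.0948 and 0.0940 without replicates 1 and 2, AT3G26050 0.175 without replicate 1, and AT1G02870 0.148 and 0.166. Again the lone array is assumed to vary like the other groups.

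The cell death list rose in whole seeds (adjusted p = 1.44e-04; adjusted p = 0.0375 with an estimated correlation), with 1 of 5 genes higher over all genes (2 without centring and with quantile normalisation) and 3 when adjusted over the list alone. Of 3 flavonoid genes 2 were higher and of 3 mucilage genes 1, and adjusted over the list alone 1 of the mucilage genes was also lower. The embryo, endosperm regulator and photosynthesis lists had 0 genes past the threshold in limma, as also when adjusted over the list alone, and adjusted p of 0.552, 0.578 and 0.519. In all, 514 probe sets were higher and 182 lower. The median over all tested probe sets was -0.23; without centring it was 0.14, with 882 higher and 61 lower, and quantile normalisation gave 759 and 111. Array weights gave 808 and 638 and an offset of 1 gave 292 and 120; with chalazal endosperm array 3 alone 376 were lower. Without whole seeds replicate 1 the counts were 144 and 26, and without replicate 2 they were 193 and 28, where the lone array is assumed to vary like the other groups. The lower count was also 115 without embryo proper replicate 2 and 114 without peripheral endosperm replicate 2.

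Compartment-enriched probe sets, higher in 1 compartment than in each of the other 5, were found mainly in the chalazal endosperm. The chalazal endosperm had 1104, the chalazal seed coat 281 and the seed coat 220. At an unadjusted p under 0.05 in limma they had 2346, 687 and 836. Both chalazal groups had 3 arrays and the other compartments 2, so the counts were not reached with equal precision. In the chalazal endosperm CYP79A2 lay 6.53 above the next compartment on the log2 scale (adjusted p = 2.34e-09). AT2G44250 (adjusted p = 1.44e-09), AT5G52140, AT4G37950, the subtilase gene SBT4.13 and AT3G03240 were enriched there too, with 1 of 3 arrays of the next compartment at or under the control background, so no exact gap is given. In the chalazal seed coat AT5G24580, AT1G43910, SWEET10, AT1G74055 and AT3G19550 were enriched, with 1 or 2 arrays of the next compartment at or under that background, and BETA-VPE lay 2.40 above the seed coat (adjusted p = 0.00390, and 0.103 without seed coat replicate 1). In the seed coat AT1G49800, AT1G11590 and DELTA-VPE lay 5.75, 5.41 and 3.32 above the next compartment, and THI2.1 (adjusted p = 1.96e-07) and AT5G62210 were enriched, with 2 and 1 arrays of the next compartment at or under that background. With an offset of 1 the chalazal seed coat count was 110 and the seed coat count 40, which was 361 with an offset at the 40th percentile. The seed coat count was 95 and 78 without seed coat replicates 1 and 2.

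The embryo proper had 2 enriched probe sets, AT1G29270 (adjusted p = 0.00945, with 2 of 3 arrays of the next compartment at or under the control background) and TBL36 (at least 2.98-fold, adjusted p = 0.0462), and 325 at an unadjusted p under 0.05. Its count was 0 without embryo proper replicate 1, peripheral replicate 1, chalazal endosperm replicate 1 or 2, or any 1 micropylar endosperm or seed coat array. It was 1 without embryo proper replicate 2, peripheral replicate 2, chalazal seed coat replicate 3 or any 1 whole seed array. The micropylar and the peripheral endosperm had 0 in limma, with 174 and 173 at an unadjusted p under 0.05, and 21 and 4 with array weights. Array weights gave 17 in the embryo proper, an offset of 1 gave 0, and an offset at the 40th percentile gave 45, with 34 and 6 in the micropylar and peripheral endosperm. Without chalazal endosperm replicate 3 the micropylar count was 3, and without micropylar endosperm replicate 1 or chalazal endosperm replicate 2 it was 1.

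The gibberellin metabolism, abscisic acid metabolism and xylem lists had 0 members named on the array, and the heat shock list had 1, which was too dim to be tested. Of 393 list members in all, 51 were named.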

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

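Of the tests reported here, the one on RNA from the adjacent chalazal seed coat was chosen after the result was seen.

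The chalazal difference was compared between endosperm (chalazal against micropylar and peripheral) and seed coat (chalazal against the rest) with an interaction term in limma, and 3886 probe sets passed at an adjusted p of 0.05. Of these, 103 were higher in the chalazal endosperm and lower in the chalazal seed coat, and 96 the reverse, each side past its own threshold, while 393 probe sets were called higher and 373 lower at both. Among list genes with a larger difference in endosperm, DME had an interaction of -4.534 (adjusted p = 6.90e-05). RCA had -3.515, SAG29 -3.477, BUBR1 -2.952, scpl48 -2.506, PRL -2.457 and FaTA -2.278, all lower in the chalazal endosperm. GAMMA-VPE had 2.184, higher there. DELTA-VPE had 4.345 (adjusted p = 1.99e-05), since it was lower in both chalazal regions but by -2.13 in endosperm and -6.48 in seed coat. LHW had -3.227, PHV -3.004, RR16 -2.297 and AT3G10320 -2.128, each higher in the chalazal seed coat with no call in endosperm. For SAG29, BUBR1, PHV, RR16 and AT3G10320 every array of 1 or more regions lay at or under the control background, and for DME, scpl48, LHW and RCA some arrays of the chalazal endosperm did, so these differences have no exact size.

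The 3812 probe sets called higher in the chalazal endosperm were weighed against 3 technical explanations. RNA from the adjacent chalazal seed coat is argued against as the lone source for most of them. A mixture cannot exceed its source, and 8.84% had a chalazal seed coat mean at or above the chalazal endosperm mean. That share is lowered by the choice of probe sets high in the chalazal endosperm. Such RNA added to that of endosperm stays open, since the check cannot see it. Of the 1104 probe sets enriched in the chalazal endosperm, the chalazal seed coat was next highest for 496. A lower labelled yield scaled up would also act on the chalazal seed coat, where the cre controls were high as well. There the same probe sets had a median difference of 0.372 (0.217 to 0.477 over the 6 pairs of arrays), against 1.845 in endosperm; the ratio of 0.202 met the limit set beforehand but the upper end of that range did not, so this cannot be told apart. A raised background of these arrays would place the probe sets near the controls; 74.48% of them exceeded the control bound on all 3 arrays, against 40.09% of all tested, just short of the 75% set beforehand, so this too cannot be told apart. A biological difference between endosperm regions, which the groups name, stays open beside these, untested.

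Chance was tested with other splits of the same arrays. For the chalazal endosperm comparison, 100 splits of the 7 arrays were fitted. The real one alone, 1 of 100, gave 3812 higher or 3509 lower, which argues against random labels of single arrays for both counts. The highest others were 3665 and 3326, from 1 of the 2 other splits that kept the 3 chalazal arrays on their own side; among the rest the highest were 1985 and 1845. For endosperm against seed coat, 1 of 100 splits reached 3852 higher and 1 of 100 reached 2996 lower, the real one in each case. The highest others were 1464 and 1756, which argues against random labels of single arrays here too. The splits moved single arrays between compartments, so they cannot tell whether another grouping of whole compartments would give as many calls. For list counts random labels cannot be excluded: 50 of 100 splits gave at least the real 1 list there (highest other 2), and 25 of 100 gave at least the real 2 in the chalazal endosperm (highest other 2).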

How the results depend on the processing

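The deposited scaling without centring, weights per group and the chalazal endosperm with array 3 alone were chosen after seeing the data. Of 260 named gene, list and family results, 167 kept their direction and their side of the threshold under all alternatives run on them (31 in all); over all of them 423 changes ended a call and 4 reversed a direction. Plastid-encoded photosynthesis genes in the chalazal endosperm turned to -0.069 with quantile normalisation and -0.051 with array 3 alone, serine carboxypeptidase-like genes in whole seeds to -0.07 without the filter, and tetraspanins in the micropylar endosperm to -0.003 without micropylar replicate 1. Median centring, planned as an alternative, became the main scaling. Array background limits what dim probe sets show, since 44.7% to 71.1% lay above the bound. Except where fewer arrays or genes are named, the cause of a change was not tested.

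With quantile normalisation whole seeds had 111 lower and endosperm against seed coat 2 lists. Without centring the embryo proper had 1716 higher, whole seeds 882 higher and 61 lower, and endosperm against seed coat 2 lists. With an offset of 1 there were 625 higher in the embryo proper, 55 higher and 9 lower in the micropylar endosperm, 690 lower in the chalazal seed coat with 1 list, 292 higher and 120 lower in whole seeds, and 0, 110 and 40 enriched in embryo proper, chalazal seed coat and seed coat. With an offset at the 40th percentile 45, 34, 6 and 361 were enriched in embryo proper, micropylar, peripheral endosperm and seed coat. Without the filter endosperm against seed coat had 2 lists. With the 60th percentile filter there were 0 lists for the embryo proper, 1 for the chalazal and 1 for the micropylar endosperm, and 1 enriched probe set in the embryo proper. With array weights there were 2549 higher and 4088 lower in the embryo proper, 321 and 109 in the micropylar endosperm, 808 and 638 in whole seeds, and 17, 21 and 4 enriched in embryo proper, micropylar and peripheral endosperm; with weights per group 2548 and 4080, 319 and 107, 805 and 649, and 18, 17 and 5. With the replicate block 1 and 8 were enriched in embryo proper and micropylar endosperm. After removing group means, arrays with the same replicate number correlated at a median of -0.002 across genes, so this median shows no general pairing. The chalazal endosperm and chalazal seed coat arrays numbered 3 correlated at 0.206, the highest of all pairs. Between different numbers the highest was 0.106, so a shared source of those 2 arrays stays open. With only the groups compared there were 2 lists for endosperm against seed coat, 52 higher and 9 lower in the micropylar endosperm, and 1 enriched in the embryo proper. With chalazal endosperm array 3 alone there were 2291 higher and 1933 lower there, 58 lower in the micropylar endosperm, 376 lower in whole seeds, and 0 and 2 enriched in embryo proper and micropylar endosperm. With an estimated correlation the embryo proper, endosperm against seed coat, chalazal and micropylar endosperm each had 0 lists, and fry gave 3 for endosperm against seed coat and 2 for the chalazal seed coat.

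Without 1 array in turn, the ranges were 254 to 1305 higher and 525 to 1780 lower in the embryo proper, 2831 to 4036 and 2392 to 3094 for endosperm against seed coat, 3031 to 4004 and 2934 to 3621 in the chalazal endosperm, 18 to 189 and 2 to 53 in the micropylar endosperm, 537 to 1135 and 437 to 1315 in the chalazal seed coat, and 144 to 586 and 26 to 270 in whole seeds. Lists ranged from 1 to 2 for endosperm against seed coat and 1 to 3 in the micropylar endosperm, with the tetraspanin median there between -0.003 and 1.292, and stayed at 2, 2, 0 and 1 in the embryo proper, chalazal endosperm, chalazal seed coat and whole seeds. Enriched counts were 0 to 2 in the embryo proper, 0 to 3 and 0 to 0 in micropylar and peripheral endosperm, 854 to 1138 in chalazal endosperm, 205 to 274 in chalazal seed coat and 78 to 244 in seed coat. The lists for endosperm against seed coat became 2 without peripheral replicate 2, chalazal seed coat replicate 2, or 1 whole seed array. Where 1 array is left in a group, it is assumed to vary like the others.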

Other observations

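Of the tests reported here, those of organelle transcripts were chosen after the result was seen.

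Of 12 tested sugar transporter genes of the SWEET family, 1 was higher and 1 lower in the embryo proper, 2 and 3 in endosperm against seed coat, 3 and 1 in the chalazal endosperm, 1 and 0 in the micropylar endosperm, 3 and 2 in the chalazal seed coat and 1 and 0 in whole seeds. As a set they passed in no comparison in camera (smallest adjusted p = 0.0967, and adjusted p = 0.352 with an estimated correlation), while fry gave adjusted p of 0.00385 in the embryo proper, 0.0286 in the chalazal endosperm, 0.00273 in the chalazal seed coat and 0.0380 in whole seeds. SWEET8 was lower in the embryo proper than in endosperm (-3.91 ± 0.47), higher in endosperm than in seed coat (5.11 ± 0.35) and higher in the chalazal than in the other endosperm (2.31 ± 0.45). SWEET9 was higher in the embryo proper (3.99 ± 0.64), and in the chalazal seed coat SWEET10 and SWEET4 were at least 94.6-fold and 4.44-fold higher and SWEET1 at least 5.79-fold lower, each from low-side arrays at or under the control background. Of 12 defensin-like genes 1 was higher and 3 were lower in the chalazal endosperm: LCR72 was at least 32.9-fold higher while PDF2.1, LCR69 and LCR24 (-3.64 ± 0.80) were lower. Among ubiquitin-conjugating enzyme genes, 3 of 12 were higher in the chalazal endosperm, namely UBC31, UBC30 (3.32 ± 0.33) and UBC32 (2.92 ± 0.46), with 0.161 as the smallest set adjusted p of that family in camera and 5.65e-04 in fry. These genes were singled out after their values were seen.

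ATG8 genes were lower in the embryo proper than in endosperm, 5 of 9, with a median of -1.35 (-1.07 to -1.35 under the 3 scalings, and -1.32 with ATG8H at its bound; 3 passed without centring and 3 with quantile normalisation), set adjusted p = 0.00427 and adjusted p = 0.169 with an estimated correlation. That endosperm mean includes the chalazal endosperm, where all 9 were higher than in the other endosperm regions. The difference need not hold against the micropylar and peripheral endosperm alone, which was not tested. In endosperm against seed coat 3 of 9 were lower, with a median of -0.51 (4 without centring and 5 with quantile normalisation), set adjusted p = 0.0604, adjusted p = 0.352 with an estimated correlation and adjusted p = 8.72e-04 in fry. In the chalazal seed coat against seed coat 2 of 9 were higher, with a median of 0.69, set adjusted p = 0.0604, adjusted p = 0.352 with an estimated correlation and adjusted p = 0.00566 in fry. The family was defined before any difference was computed and singled out here after its values were seen.

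In the micropylar against the peripheral endosperm, tetraspanins (2 of 13 higher, 1 with quantile normalisation, set adjusted p = 0.00493), expansins (0 of 16, 0.0413) and GSTU genes (1 of 9, GSTU23 at least 6.35-fold; 0.0349) moved up, and plastid-encoded photosynthesis (0 of 43 past the threshold in limma, 6.67e-04) and gene expression genes (0 of 19, 0.00788) moved down. With an estimated correlation these were adjusted p = 0.352 for the first 3 and adjusted p = 0.672 and adjusted p = 0.639 for the plastid families. In fry they were 0.0620, 0.0900 and 0.0175 for the first 3 and 0.579 and 0.478 for the plastid families. Without micropylar replicate 1 the tetraspanins had 0.248, with a median of -0.003, and GSTU genes 0.0840; without peripheral replicate 1 GSTU genes had 0.144. Without peripheral replicate 2 the expansins had 0.0943 and the plastid gene expression genes 0.191, and without chalazal endosperm replicate 2 the expansins had 0.0580. Without micropylar replicate 2 the expansins had 0.273, GSTU genes 0.0516 and the plastid families 0.833 and 0.756. In whole seeds GH9 endoglucanases (1 of 13 higher, 2 without centring, GH9B5 at 2.45 ± 0.53; 0.00177), serine carboxypeptidase-like genes (2 of 23, 0.00997) and tetraspanins (0 of 13, 0.0448) moved up and plastid gene expression genes (0 of 19, 0.00433) down, with adjusted p = 0.156, adjusted p = 0.156, adjusted p = 0.534 and adjusted p = 0.639 with an estimated correlation, and 7.11e-04, 0.0144, 0.174 and 0.209 in fry. Without whole seeds replicate 1 the plastid gene expression genes had 0.671, and with quantile normalisation 0.746. Tetraspanins had 0.107 and 0.0940 without whole seeds replicates 1 and 2, 0.0607 without embryo proper replicate 2, 0.0915 without micropylar replicate 2, 0.0616 without peripheral replicate 2, 0.0625 without chalazal endosperm replicate 2 and 0.0586 with quantile normalisation. The median of the serine carboxypeptidase-like genes, 0.39, was -0.07 without the filter. The other families passed in no comparison in camera, with smallest adjusted p of 0.253 (CYP71B), 0.537 (RALF-like), 0.344 (TON1 recruiting motif), 0.0604 (UDP-glucosyltransferases), 0.315 (XTH), 0.112 (bZIP), 0.0967 (beta-glucosidases), 0.251 (defensin-like), 0.210 (trichome birefringence-like) and 0.0576 (ubiquitin-specific proteases). With the SWEET and ubiquitin-conjugating enzyme genes these are 12 families, of which fry called 10 in 1 or more comparisons. Its smallest adjusted p were 4.98e-04 (trichome birefringence-like and ubiquitin-specific proteases), 0.00106 (CYP71B), 0.00171 (beta-glucosidases), 0.00197 (bZIP), 0.00571 (XTH), 0.00739 (UDP-glucosyltransferases) and 0.0284 (defensin-like), while TON1 recruiting motif (0.0660) and RALF-like genes (0.219) passed in none.

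The probe sets higher in whole seeds than in the compartment mean were weighed against unequal shares of the compartments. A mixture cannot exceed its highest part, and 17 of 514, or 3.31%, exceeded their highest compartment by over 1 on the log2 scale (49 by any amount). A mixture of equal shares also stays under its highest part, so this check cannot tell unequal from equal shares. The compartment mean is one of log2 values, which can lie under the log2 value of an equal mixture. The highest compartment was the seed coat for 370 and the chalazal seed coat for 91. In limma 0 probe sets were higher in whole seeds than in each of the 6 compartments, with 15 at an unadjusted p under 0.05, and among named genes OCT1 lay furthest above its highest compartment, by 3.16. Tissue outside the 6 captured compartments was not tested and stays open.

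Plastid-encoded transcripts were higher and mitochondria-encoded ones lower in endosperm than in seed coat, and for each part a changed share of RNA without poly(A) tails was weighed. The plastid-encoded photosynthesis medians were 1.29, 1.07 and 0.95 and the mitochondria-encoded ones -0.91, -1.13 and -1.15 with centring, without it and with quantile normalisation. The signal of 25S rRNA, which lacks such tails, differed by -0.45 (SE 0.142), but the cre hybridisation controls went the same way, by -0.30, and relative to them the 25S difference was -0.152 (SE 0.09). By region that log2 ratio was -0.85 in chalazal, -1.22 in micropylar and -1.33 in peripheral endosperm, -0.94 in chalazal seed coat and -1.02 in seed coat. With a difference within 2 SE of 0, the 25S signal decided neither part. The same share cannot be both larger and smaller in endosperm, and the plastid and mitochondrial medians lay on opposite sides under every scaling. A changed share thus cannot account for both parts at once. For either part alone it cannot be told apart from a biological difference between the regions, a hypothesis left untested. Other technical causes were not run.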
